A study of Mus musculus with 6 samples.

How the data were processed

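RNA was sequenced from NP-binding memory B cells sorted from mouse spleen, in 3 wild-type libraries and 3 libraries labelled as lacking Bnip3l and Bnip3. Per the labels' protocols, RNA from about 1000 sorted cells per library was made into amplified cDNA libraries, enriched for polyadenylated RNA, with a commercial kit for single-cell RNA. The submitters' processing notes name CASAVA, STAR, edgeR and R 3.6.3 and the genome build mm10, without their roles. The authors deposited 1 table of raw read counts per gene symbol, not normalized, with 35186 symbols and 6 columns. The counting tool, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping genes and of antisense pairs cannot be told apart, and genes with near-identical copies are uncertain. Some symbols in the table had been turned into dates by a spreadsheet and are not named. Columns were matched to samples by their names, and 0 columns were left unmatched.

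Counts were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1). Genes were kept by filterByExpr (minimum count 10), libraries were scaled by TMM, and the DKO group was compared with the WT group by the quasi-likelihood F test with robust estimation, over all 6 libraries and with no covariate. P-values were adjusted by the Benjamini-Hochberg method over the 8895 genes kept, with a threshold of 0.05. TMM factors were 0.812, 0.695 and 0.785 for WT libraries 1, 2 and 3 and 1.28, 1.38 and 1.28 for DKO libraries 1, 2 and 3. Standard errors are the log2 fold change divided by the square root of the F statistic. Normalized CPM divide a count by the library size of the kept genes times this factor. With 312908 to 517057 counts per library the depth was low; 1 count was worth 1.84 to 5.25 normalized CPM. Folds against a group with 0 counts set the other group's mean normalized CPM against a floor of 3 counts over the group. Floors cover counting error only, since amplified reads are not independent molecules.

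The 42 gene lists, of which 29 were pathway lists and 13 marker lists, the tests, and the rule for named genes were set before the data were examined. Lists with at least 5 kept genes were tested with camera at a preset correlation of 0.01, adjusted over the 37 lists tested. Named genes were Bnip3l and Bnip3; the 14 genes in each direction with the smallest p among those past the threshold with groups that did not overlap, filled to 6 by smallest p where fewer passed, leaving out immunoglobulin segments, predicted genes and pseudogenes; up to 4 members with the smallest p of each list; and the immunoglobulin constant genes that were tested. Since 0 genes passed, the 6 named in each direction are values that did not pass, and the immunoglobulin genes Igkc, Ighg1 and Ighm, which were not tested, the most abundant mitochondrial gene mt-Co1, genes abundant in 1 library (Kif1b, Pomt2, Mapre1), and Actb and Cd79a were chosen after their values were seen.

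Library measures were compared by exact two-sided permutation tests, which cannot give a p under 0.1 with 3 libraries against 3. Correlations between libraries are Spearman correlations across genes, which are not independent replicates. Gene positions and exonic lengths are from GENCODE mouse release 21 on mm10, matched by symbol; 31032 of the 35186 symbols (88.2%) had 1 matching gene. Python 3.11.15 with scipy 1.17.1 was used for these steps.

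The alternatives tried were other scalings (the size factors of DESeq2, TMMwsp, upper quartile), no filter on low counts, a mean CPM of at least 10, DESeq2 1.42.0, limma-voom with quality weights, no robust estimation, an adjusted p of 0.1, leaving out immunoglobulin genes or mitochondrial and ribosomal protein genes, the replicate number as a block, each replicate left out in turn, and for the lists an estimated correlation and fry. No scaling factor and thinning to equal depth were added after the data were seen. The edgeR steps were tested on simulated counts with 200 of 8895 genes changed. With the spread of the DKO against WT data, the test recovered 0 of 67 genes at a log2 fold change of 2, 0 of 67 at 4 and 0 of 66 at 6, of which 57, 55 and 60 had passed the filter, with 0 false calls. With a coefficient of variation of 0.2 it recovered 92.5%, 100% and 100%, with 9 false calls. A simulated list shifted by 2 on the log2 scale had an adjusted p of 8.93e-14, and 0 other lists were called.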

Results

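Gene expression was measured by RNA sequencing in memory B cells sorted from mouse spleen for binding the hapten antigen NP. The cells came from wild-type animals (WT, 3 libraries) and from animals labelled as lacking both Bnip3l, also called Nix, and Bnip3 (DKO, 3 libraries). Both genes encode outer mitochondrial membrane proteins that act as receptors for mitophagy, the removal of mitochondria by autophagy. Each library was made from about 1000 cells. Total counts were 312908, 500527 and 319863 in WT libraries 1, 2 and 3, and 444461, 517057 and 514854 in DKO libraries 1, 2 and 3, so that 3 counts in a library corresponded to between 5.52 and 15.8 normalized CPM (counts scaled to the effective library size). The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

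The targeted genes were read first, and the mean of Bnip3l went against the labels, with groups that overlapped. Bnip3l (chromosome 14, 66985239 to 67008877, mm10) had 1, 8 and 0 counts in the WT libraries and 10, 16 and 41 counts in the libraries labelled DKO, or 12.04 ± 16.55 against 43.8 ± 31.0 normalized CPM (SD, n = 3). Its log2 fold change, DKO against WT, was 1.76 (SE 1.19, edgeR adjusted p = 0.539). Once normalized, WT library 2 lay above DKO libraries 1 and 2, and without it the value was 3.94. Bnip3 (chromosome 7, 138890836 to 138909519) had 25, 62 and 6 counts in the WT libraries and 2, 24 and 11 in the libraries labelled DKO, or 134 ± 104 against 23.3 ± 19.9 normalized CPM (SD, n = 3). Its log2 fold change was -2.50 (SE 1.13, edgeR adjusted p = 0.412), and these groups overlapped too. Neither gene passed the test. Which exons were deleted is not in the labels, and counts per gene do not separate a deleted exon from the rest of a transcript, so these counts do not settle the genotypes. Every direction below is between libraries as labelled.

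**Figure D1:**
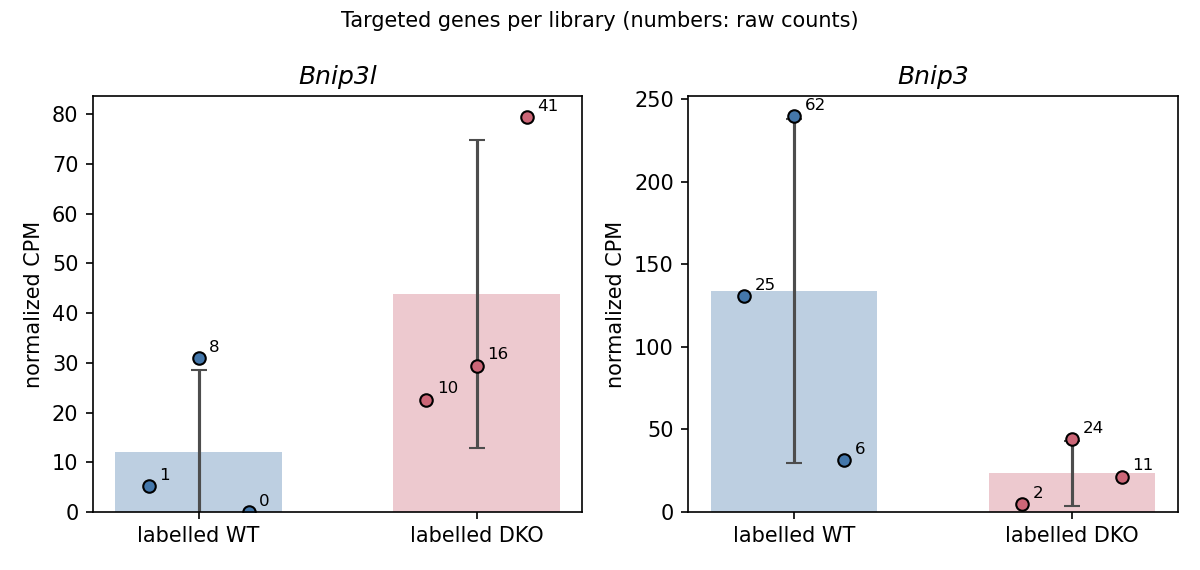
Normalized CPM of Bnip3l and Bnip3 in each library labelled WT or DKO; bars are group means, error bars 1 SD (n = 3), points are libraries and the numbers beside them raw counts. Bnip3l has 10, 16 and 41 counts in the libraries labelled DKO and 1, 8 and 0 in those labelled WT.

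The 6 genes in each direction with the smallest p, among those whose groups did not overlap, had almost no counts in 1 group. None passed the adjusted test. The rule left out immunoglobulin segments, predicted genes and pseudogenes, and it set beforehand that all 3 libraries of a group lie on 1 side. Higher in all 3 libraries labelled DKO were Rasal3, a Ras GTPase-activating protein of blood cells (187 ± 74.4 against 1.75 ± 3.03 normalized CPM, SD, n = 3), Rcan3, a regulator of calcineurin (198 ± 122 against 4.78 ± 0.793), and Usp39, a splicing factor (120 ± 62.6 against 1.29 ± 2.23). Cap1, an actin regulator, and the cytokine gene Il6 followed, with log2 fold changes of 5.28 (SE 1.24) and 6.26 (SE 1.47). The fitted value of Rasal3 was 6.58, or 9.21 without WT library 3, and without WT library 2 Usp39 went from 6.03 to 8.51 and Il6 to 8.75. Calcoco2 had 21, 52 and 24 counts in the libraries labelled DKO and 0 in each WT library. This made it at least 13.5-fold higher in the mean against a floor of 3 counts over the WT group. Lower in all 3 libraries labelled DKO were Rbm19, a ribosome biogenesis factor (5.22 ± 3.68 against 465 ± 298 normalized CPM), Tnfrsf1a, a receptor for tumour necrosis factor (5.18 ± 2.76 against 422 ± 296), and Dohh, an enzyme of hypusine formation (6.12 ± 3.72 against 564 ± 391). Adam11 and C1qtnf2 had log2 fold changes of -6.60 (SE 1.34) and -5.95 (SE 1.27), the former -7.93 without DKO library 3. Cmtm3 had 9, 112 and 11 counts in the WT libraries and 0 in each library labelled DKO, at least 89.7-fold lower in the mean against a floor of 3 counts over that group. Of its counts 112 were in WT library 2, without which the fitted log2 fold change went from -9.01 to -7.28. The edgeR adjusted p of each of these 12 genes was 0.389.

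Of the 8895 genes tested, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, while at an unadjusted p under 0.05 there were 488 genes higher and 586 lower in the libraries labelled DKO. DESeq2 called 47 genes higher and 168 lower, among them all 12 genes named above, and limma-voom called 0. The groups did not overlap for 1142 genes higher and 568 lower, 19.2% of the tested genes where chance gives 10%. All genes share the same 6 libraries, so a difference between whole libraries, as in the number of genes counted, can move this share. It was not computed for other splits of the libraries. The biological coefficient of variation was 0.915, and 29.7% of the tested genes had over 50% of their summed CPM in 1 library. Scaling also moved all genes together: the median log2 fold change of the tested genes was -0.17 after TMM scaling and 0.62 with library totals alone, so each fold change is to be read against that median, and 13 of the 37 list medians given below turn from below to above 0 with library totals alone. Leaving out 1 library moved the fold change of 58 of the 82 named genes followed by over 1.5-fold. In simulated counts with this spread and a 6 log2 change, 0 of 66 changed genes were recovered, 60 of which had passed the filter.

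Transcripts encoded by the mitochondrial genome, the 11 tested of the list fixed for the proteins of oxidative phosphorylation made inside mitochondria, were all at lower values in the libraries labelled DKO, with a median log2 fold change of -2.53. The 13 members counted held 7.60%, 6.23% and 1.94% of all counts in WT libraries 1, 2 and 3, and 2.87%, 1.503% and 0.998% in libraries 1, 2 and 3 labelled DKO, so that WT library 3 lay below DKO library 1 (exact two-sided permutation p = 0.2, n = 3 against 3, smallest possible 0.1). The most abundant member, mt-Co1, a subunit of cytochrome c oxidase, had 8138, 13602 and 2713 counts against 3640, 2463 and 1643. Log2 fold changes were -3.38 (SE 1.15) for mt-Co2, -2.78 (SE 1.05, or -3.83 without DKO library 1) for mt-Co3, -2.53 (SE 0.96) for mt-Nd4l and -2.88 (SE 1.46) for mt-Nd3. These genes had far fewer counts than mt-Co1, for a reason that was not tested. How reads matching more than 1 place in the genome were treated is not known, so these fold changes are uncertain. Counts of mt-Co2 were 43, 67 and 4 against 12, 6 and 5, with groups that overlapped. They were 25, 33 and 13 against 15, 3 and 4 for mt-Co3, and 25, 17 and 11 against 9, 5 and 7 for mt-Nd4l. For mt-Nd3 they were 323, 285 and 54 against 109, 63 and 28. Of the 37 lists tested, this was the 1 that camera called (adjusted p = 2.27e-05). The call was lost with an estimated correlation (adjusted p = 0.872) and in fry (adjusted p = 0.182), and 0 of its members passed the test, adjusted over the list alone or over all genes. Without scaling factors the list's median was -1.79.

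**Figure D2:**
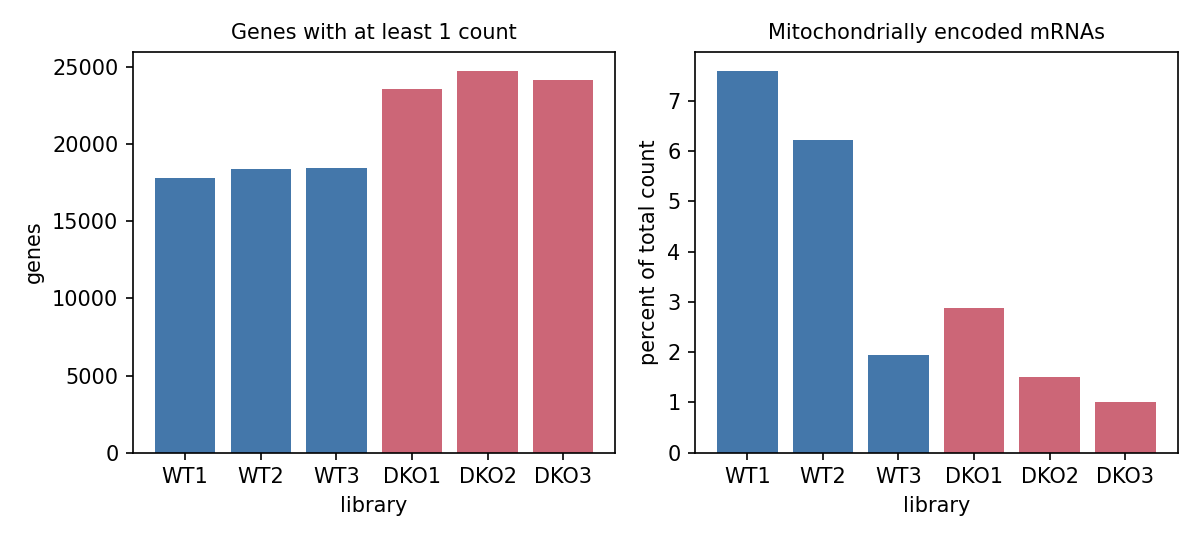
Left, number of genes with at least 1 count; right, percent of the total count from mitochondrially encoded mRNAs, in each library labelled WT (blue) or DKO (red). Every library labelled DKO has more genes with a count (23580 to 24787) than every WT library (17831 to 18486), and the mitochondrial shares of WT library 3 (1.94%) and DKO library 1 (2.87%) cross.

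Genes of autophagy and mitophagy showed values in both directions. Of 20 core autophagy genes tested, 9 had log2 fold changes above 0 and 11 below (median -0.04, camera adjusted p = 0.847). Atg2b, a lipid transfer protein of the forming autophagosome, had 8, 7 and 7 counts in the WT libraries and 91, 198 and 200 in those labelled DKO (log2 fold change 3.17, SE 1.02). Atg7, the enzyme that activates the ubiquitin-like proteins of autophagy, had 4, 9 and 2 against 89, 50 and 71, and Atg16l1 had 29, 30 and 10 against 2108, 242 and 376 (4.21, or 2.59 without DKO library 1). Ulk1, the kinase that starts autophagy, lay the other way at -3.42 (SE 1.31), or -1.94 without WT library 2. Among 12 other mitophagy genes, 6 lay above 0 and 6 below (median -0.25, camera adjusted p = 0.926). Park2, which encodes parkin, had 10, 46 and 24 counts against 11, 15 and 14, and Usp30, the deubiquitinase that opposes parkin, 0, 90 and 130 against 12, 12 and 6. For the lysosome list, 9 of 21 genes lay above 0 (median -0.71, camera adjusted p = 0.985), with Npc2 at 3.53 (SE 1.10) and Lamp1 at 3.17 (SE 1.28), the latter 7.66 without WT library 2. The cholesterol transporter gene Npc1 and the sulfatase gene Galns lay the other way, at -2.38 (SE 1.02) and -2.98 (SE 1.32), or -1.53 and -1.39 without WT library 1. None of these genes passed the edgeR test; DESeq2 called Atg2b (adjusted p = 0.0444) and Atg16l1 (adjusted p = 0.0305).

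Nuclear genes for mitochondrial functions lay in both directions, and camera called no list of them. Of 17 nuclear oxidative phosphorylation genes, 10 lay above 0 (median 0.55, camera adjusted p = 0.403), with Sdhc, a subunit of succinate dehydrogenase, at 2.99 (SE 1.12) and Ndufv3 of complex I at 2.83 (SE 1.33), or 8.10 without WT library 2. Of 15 genes of mitochondrial proteostasis, 9 lay above 0 (median 0.97, camera adjusted p = 0.403), and the inner membrane protease genes Spg7 and Afg3l2 had values of 2.67 (SE 1.00) and 3.82 (SE 1.48), the latter between 2.35 and 7.88 with 1 library left out. The chaperonin gene Hspd1 was at -1.64 (SE 0.90). Of 21 mitochondrial ribosome genes 12 lay above 0 (median 0.27, camera adjusted p = 0.847). Mrpl11 was at 4.59 (SE 1.33), Mrpl30 at 3.89 (SE 1.34) and Mrps15 at 2.91 (SE 1.16), while Mrpl1, with 7, 15 and 12 counts against 5, 4 and 5, was at -2.44 (SE 0.93). Without WT library 1 Mrpl30 was at 7.40, and without WT library 2 Mrpl11 was at 7.08 and Mrps15 at 4.56. In the mitochondrial biogenesis list (11 genes, median -0.89, camera adjusted p = 0.926), Ppargc1a, the coactivator known as PGC-1alpha, was at -3.79 (SE 1.07) and passed the test adjusted over the list alone (adjusted p = 0.0458) but not over all genes (edgeR adjusted p = 0.390; DESeq2 adjusted p = 0.0425). Tefm, the mitochondrial transcription elongation factor, was at 2.73 (SE 1.11). Mief1, an adaptor for mitochondrial fission, was at 3.40 (SE 1.05) in the mitochondrial dynamics list (11 genes, median 0.11, camera adjusted p = 0.799), where Rhot1, which links mitochondria to motor proteins, was at 1.47 (SE 0.94) and Dnm1l, the fission GTPase, at -1.31 (SE 0.91). In the TCA cycle list (14 genes, median -0.01, camera adjusted p = 0.847) Mdh2 was at 4.68 (SE 1.43), or 7.31 without WT library 3, and Cs, citrate synthase, at 1.81 (SE 0.99). Mpc2, a subunit of the mitochondrial pyruvate carrier, was at -2.78 (SE 1.89) and rested on 709 counts in WT library 2, without which its value was 1.44.

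Metabolic and stress lists had no camera call. Median log2 fold changes were -1.01 for glycolysis (9 genes, camera adjusted p = 0.642), where Ldhb had 28, 0 and 339 counts in the WT libraries, -0.28 for fatty acid oxidation (16 genes, 0.903), -0.93 for fatty acid synthesis (17 genes, 0.847) and -0.95 for cholesterol synthesis (12 genes, 0.847). In the fatty acid synthesis list, where 5 genes lay above 0 and 12 below, Acly, which makes cytosolic acetyl-CoA, was at 2.59 (SE 1.17). The desaturase gene Fads1 was at -3.07 (SE 1.25), or -0.66 without WT library 2. Medians were -0.21 for antioxidant genes (10 genes, camera adjusted p = 0.847), -0.29 for ferroptosis (9 genes, 0.926), 0.14 for apoptosis (14 genes, 0.847) and -0.17 for the hypoxia response (17 genes, 0.926). In the apoptosis list the adaptor Fadd was at 3.07 (SE 1.20), or 4.26 without WT library 3, and the survival factor Mcl1 at 1.77 (SE 1.05). Apaf1, the scaffold of the apoptosome, was at -4.20 (SE 1.73), or -0.63 without WT library 3. In the hypoxia list the oxygen sensor Egln1 was at 4.27 (SE 1.36) and the nuclear receptor gene Rora at -2.48 (SE 1.22), or -1.12 without WT library 1. The integrated stress response was at 0.38 (6 genes, camera adjusted p = 0.823). Of 20 endoplasmic reticulum stress genes 16 lay above 0 (median 0.69, camera adjusted p = 0.403), led by Herpud1 at 3.88 (SE 1.32), or 7.39 without WT library 1, and the stress sensor Atf6 at 2.77 (SE 1.08). The disulfide isomerase gene Pdia3 was at -1.90 (SE 1.05), or -0.90 without WT library 2. Cell cycle genes (18 genes, 0.926), cytosolic ribosome genes (25 genes, 0.926) and MYC and nucleolar genes (12 genes, 0.926) had medians of 0.15, 0.15 and 0.46. The list of immediate early and dissociation stress genes had 4 tested members, too few for a list test, with a median of 0.46.

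Genes of B cell function were mixed as well. Of 10 NF-kB target genes, 8 lay below 0 (median -1.16, camera adjusted p = 0.847). Adjusted over the list alone, Il6 was higher (adjusted p = 0.0116) and Nfkb1 lower (log2 fold change -3.44, SE 1.11); over all genes neither passed. Nfkbie, an inhibitor of NF-kB, was at -5.08 (SE 2.04), or -1.997 without WT library 1. Interferon response genes (19 genes) had a median of -0.70 (camera adjusted p = 0.986). In the B cell receptor signalling list (18 genes, median -0.15, camera adjusted p = 0.985), the adaptor gene Blnk had 106, 21 and 58 counts in the WT libraries and 25, 36 and 37 in those labelled DKO, and Pik3ap1 had 3, 1 and 4 against 16, 49 and 32. The exchange factor gene Vav2 was at -2.83 (SE 1.23), or -1.95 without WT library 2. In the list for MHC class II presentation 5 of 6 genes lay below 0 (median -2.04, camera adjusted p = 0.424). The lysosomal protease gene Lgmn was at -3.41 (SE 1.26), or -1.27 without WT library 2, and the costimulatory gene Cd86 at -2.48 (SE 1.09), or -1.36 without WT library 3. H2-Ob was at 1.78 (SE 0.95). H2-Eb1, at -3.00 (SE 1.48), rested on 139 counts in WT library 2, without which its value was 1.54. The 9 immunoglobulin constant genes counted had too few counts to be tested. Together they had 6, 58 and 15 counts in the WT libraries and 26, 36 and 47 in those labelled DKO. Of these, Igkc had 0, 1 and 0 in the WT libraries and 0, 2 and 0 in those labelled DKO. Ighg1 had 4, 14 and 2 against 0, 1 and 2, and Ighm had 0 in each WT library and 5, 0 and 5 in those labelled DKO.

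A test for change in either direction, fry's mixed p, passed for 6 lists: mitochondrial proteostasis (adjusted p = 0.011), endoplasmic reticulum stress (0.011), NF-kB targets (0.011), the mitochondrial ribosome (0.0213), core autophagy (0.0302) and neutrophil markers (0.0302). It was planned as an alternative to camera, not as the main test, and compares a list with no other genes. Fry's directional test called 0 lists (smallest adjusted p = 0.072).

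Markers of B cell subsets and of other spleen cells gave no camera call. Memory B cell markers (9 genes) had a median log2 fold change of 0.19 (camera adjusted p = 0.847), with the transcription factor genes Bach2 and Foxo1 at 2.16 (SE 1.21) and 1.66 (SE 0.97) and the tetraspanin gene Cd9 at -2.34 (SE 1.04), or -1.35 without WT library 2. Bach2 was at 4.41 without WT library 3. Medians were 0.56 for follicular and naive B cells (6 genes, camera adjusted p = 0.642), -1.94 for marginal zone and B-1 B cells (8 genes, 0.403), -0.69 for germinal centre B cells (9 genes, 0.642) and -0.29 for plasma cells (8 genes, 0.986). Among these, Notch2 was at -2.67 (SE 1.04), the complement receptor gene Cr2 at -1.65 (SE 0.90) and Neil1 at -3.22 (SE 1.46). For T cells the median was -0.99 (8 genes, 0.823), with Bcl11b at -3.38 (SE 1.37) or -0.73 without WT library 3. For monocytes and macrophages it was -0.15 (10 genes, 0.823), with Lyz2 at 3.15 (SE 1.32), Itgam at 2.41 (SE 1.14) and the transcription factor gene Spic at -1.27 (SE 0.99). Without WT library 3 Lyz2 was at 4.48 and Itgam at 3.76. For neutrophils it was 0.50 (5 genes, 0.926), with Ltf at -2.92 (SE 0.96) and Cxcr2 at 2.92 (SE 1.65), or 0.53 without DKO library 3. It was -0.85 for dendritic cells (6 genes, 0.847). For stromal and endothelial cells it was -1.85 (10 genes, 0.403), with Col1a1 at -3.66 (SE 1.20) or -2.26 without WT library 1. Markers of NK cells (3 genes tested, Il2rb at 2.47, SE 0.97), erythroid cells (3 genes, median 0.40) and platelets (2 genes) were too few for a list test. The platelet integrin gene Itga2b, at -3.22 (SE 0.99), passed adjusted over the list alone (adjusted p = 0.0136) and not over all genes (adjusted p = 0.390). Camera's direction was up, against a median below 0, for core autophagy, the lysosome, the TCA cycle, antioxidant genes, the hypoxia response, interferon response, B cell receptor signalling, plasma cells, and monocytes and macrophages, and down, against a median above 0, for neutrophils.

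The libraries themselves differed with the labels. Those labelled DKO had 23580, 24787 and 24170 genes with a count and the WT libraries 17831, 18410 and 18486 (exact two-sided permutation p = 0.1, the smallest possible with n = 3 against 3; adjusted over the 12 library measures compared, 0.3). After thinning each library to 312908 counts the means were 22470 ± 356 against 17670 ± 832 genes (SD, n = 3). The 10 most abundant genes took 13.2%, 8.78% and 12.9% of the counts in the WT libraries and 4.80%, 2.92% and 6.20% in those labelled DKO. Some genes were abundant in 1 library alone: Kif1b had 11676 counts in WT library 1 and 309 to 810 elsewhere, Pomt2 had 10672 in WT library 3 and 10 to 70 elsewhere, and Mapre1 had 15434 in DKO library 3 and 12 to 191 elsewhere. Among genes that B cells transcribe, counts were uneven, and some were close to 0 in every library. Actb had 0, 0 and 0 in the WT libraries and 0, 2 and 3 in those labelled DKO. Cd79a, a subunit of the B cell receptor, had 3, 0 and 0 against 0, 2 and 4. The B cell surface gene Ms4a1 had 28, 0 and 8 against 42, 70 and 65 and Gapdh had 19, 68 and 12 against 25, 60 and 13. Of 1456 olfactory, vomeronasal and trace amine receptor genes, 37.6% to 42.7% had a count in the WT libraries and 58.2% to 64.4% in those labelled DKO. Ribosomal protein genes took 0.238% ± 0.0735 of the counts in the WT libraries and 0.227% ± 0.0184 in those labelled DKO (SD, n = 3, exact two-sided permutation p = 0.8). Immunoglobulin genes took 0.0761% ± 0.0183 and 0.0739% ± 0.00787 (SD, n = 3, exact two-sided permutation p = 0.8). How far the gene and list values above reflect memory B cell RNA is thus not settled.

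**Figure D3:**
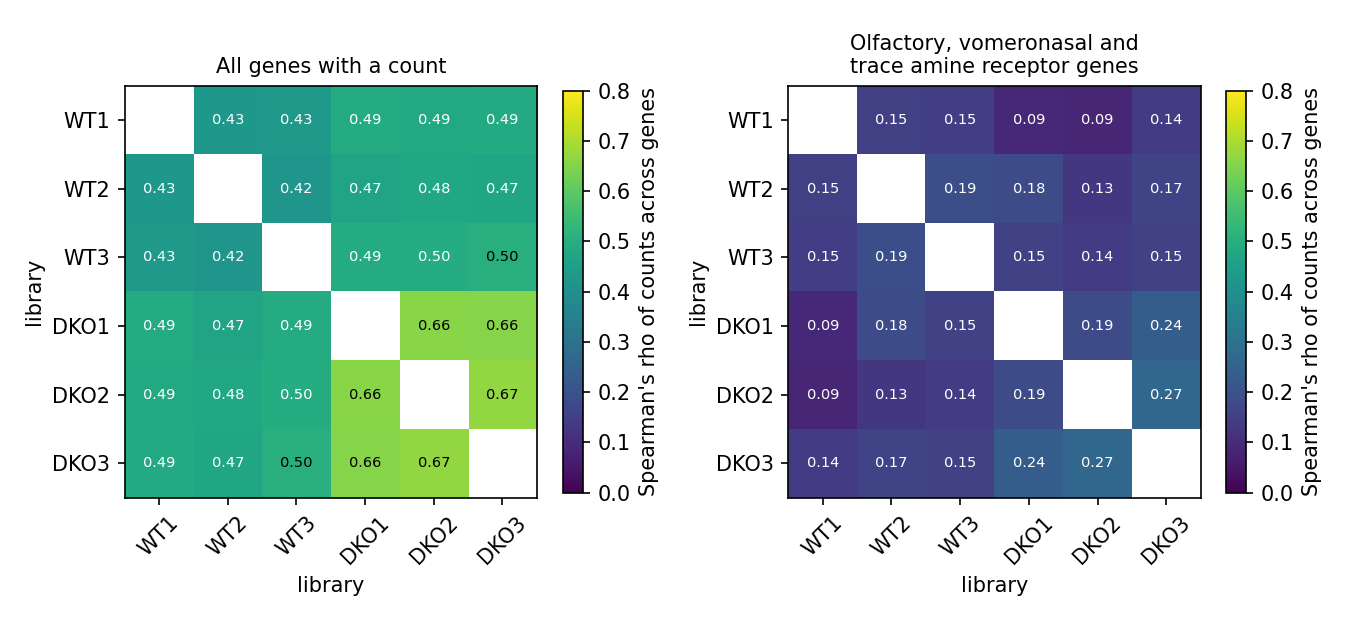
Spearman correlations of counts between pairs of libraries across all genes with a count (left) and across olfactory, vomeronasal and trace amine receptor genes (right); colour and numbers give rho. Across all genes with a count, pairs labelled DKO lie at 0.655 to 0.671 and WT pairs at 0.418 to 0.429; across the receptor genes, pairs labelled DKO lie at 0.187 to 0.265 and WT pairs at 0.149 to 0.192.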

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

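Thinning to equal depth and no scaling factor were chosen after seeing the data. The count of 0 genes in each direction held under all alternatives except 2. Without a filter on low counts 22 genes were higher and 108 lower, and 102 of these 130 had over 90% of their summed CPM in 1 library. DESeq2 called 47 higher and 168 lower, of which 46 and 112 had groups that did not overlap and 40 in all had over 90% of their summed CPM in 1 library; 51 genes were called by both. The cause was not tested. Whether the replicate numbers pair the samples stays open. Deviations of same-numbered libraries correlated at 0.023, 0.026 and 0.037, and those of all other pairs at -0.024 to -0.004. Each WT library thus correlated best with its own number, but these correlations are small. With the replicate block 0 genes and 1 list were called. Log2 fold changes ranged from 1.12 to 3.94 for Bnip3l and from -3.24 to -1.65 for Bnip3, never past the threshold; thinned, Bnip3l had too few counts to be tested. H2-Eb1 ranged from -3.50 to 1.54 when 1 replicate was left out, turning without WT replicate 2, as did Mpc2, from -3.28 to 1.44. Mpc2 was also at 0.37 in limma-voom, and the cause was not tested. The other genes followed kept their direction under all alternatives that tested them. The camera call fell from 1 list to 0 with an estimated correlation (the mitochondrial mRNAs at adjusted p = 0.872), to 0 with fry (0.182), and to 0 without mitochondrial and ribosomal protein genes, which removes the list. Leaving out each replicate in turn called 1 list each time at the preset correlation, with adjusted p from 1.08e-07 to 0.00374 for the mitochondrial mRNAs. The other lists stayed uncalled by camera and by fry's directional test, with 46 of 536 directions unlike the main one. List medians also depended on the fit. With the replicate block, several turned from below to above 0, such as antioxidant genes (-0.21 to 1.15), mitochondrial biogenesis (-0.89 to 0.50) and the lysosome (-0.71 to 0.23). Marginal zone and B-1 B cell markers went from -1.94 to -0.48, and MHC class II presentation from -2.04 to -1.25. At this depth and spread, single-gene changes even of 6 on the log2 scale were not recovered in simulations.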

Other observations

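The tests of the mitochondrial list, of other splits, of genes matched on counts, and of read rates in the libraries labelled DKO were chosen after the results were seen. A set of 28 genes had at least 10 counts in each library labelled DKO and 0 in each WT library, against 1 gene the other way and at most 3 in the other splits of the 6 libraries. This moved with the larger number of genes counted in each library labelled DKO: at any count, 1144 genes were in all 3 of them and in no WT library, and 44 the other way. Beside Calcoco2 it held Stx17, a syntaxin of autophagosome fusion, with 13, 41 and 31 counts, and Stpg1, with 52, 40 and 15, both named, like the genes of the next paragraph, after their values were seen. At an unadjusted p under 0.05 the real split gave 1074 genes and the highest other split 599. For genes past the threshold, all 10 of 10 splits gave as many (0 in the real one, highest other 0), and 10 splits are too few for a share under 0.05.

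Some abundant B cell transcripts were close to uncounted, such as Cd74 with 2, 11 and 0 counts in the WT libraries and 3, 5 and 4 in those labelled DKO, although others, such as Ms4a1 and Blnk, were not, and Neb, a giant gene of muscle, had 64 to 248. Olfactory, vomeronasal and trace amine receptor genes, silent in B cells, had a count for 37.6% of 1456 genes in the library with the fewest, above the bound of 2% set beforehand for shallow sequencing of RNA alone. For the read rates here and below, each count was capped at the 99th percentile of its library's counts above 0. Amplified genomic DNA is a candidate source of the receptor genes' counts: the read rate per kilobase of these genes was 0.136 to 0.405 of that of the B cell receptor and MHC class II lists, between the bounds of 0.5 and 0.1 set for it, so this source remains open. It was not tested as a cause of the B cell transcripts close to uncounted. The counting tool and its strand setting are not given, so the part of the counting in either pattern could not be tested. Receptor genes 1 to 50 kb apart deviated together no more than those on other chromosomes (excess correlation -0.01). With 1057 such pairs the highest of 100 shuffles gave a correlation of 0.045, so a small excess from long amplified stretches of DNA could be missed. For 9837 pairs of other genes the excess was 0.014. Their correlation of 0.015 lay just under the highest of 100 shuffles, 0.016, so long stretches are neither shown nor excluded.

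Libraries labelled DKO resembled each other more than WT libraries did, with Spearman correlations of 0.655 to 0.671 against 0.418 to 0.429 over 31134 genes. Sequencing depth does not account for it, nor do genes counted mostly in 1 library. The lowest DKO pair stayed 0.208 above the highest WT pair when thinned to equal totals, and 0.292 without those genes. Thinning equalizes reads and not the molecules captured, so fewer molecules in the WT libraries were not tested as a cause. After thinning, the WT libraries had 17670 ± 832 genes with a count and those labelled DKO 22470 ± 356 (SD, n = 3). Among receptor genes the gap between pairs was -0.005, although the other DKO pairs, at 0.236 and 0.265, still lay above every WT pair. It was 0.141 among genes matched to the receptor genes on counts. A larger share of reads from RNA in the libraries labelled DKO may be a cause: the receptor genes' read rate (1.62 against 1.98) and its ratio to that of the B cell lists (0.188 against 0.255) had lower means there, although WT library 1 had the lowest ratio (0.136), while the read rate of the B cell lists (8.64 against 8.78 reads per kilobase, scaled to library totals), the ribosomal protein share (0.227% against 0.238%) and the mitochondrial share (1.79% against 5.26%) were not higher, so it remains open. Genotype goes with the same split of the libraries and stays open, untested.

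The mitochondrial mRNAs moved as a block. Scaling is argued against as the whole cause by their median of -1.79 without a scaling factor. With each library left out in turn the median was -2.88 to -2.05, so its value did not rest on 1 library alone. Whether it differs from 0 without a given library stays open, since the median standard error of a member was 1.98. Their estimated correlation within groups was 0.854, which the preset value ignores, so one shared fluctuation of mitochondrial content between libraries may give the call. As many lists were called in 5 of the 10 splits, 1 in the real split and at most 1 in the others, too few splits for a share under 0.05. In the split that put WT library 1 with DKO libraries 2 and 3, another list was called (the mitochondrial mRNAs at camera adjusted p = 0.601). The mitochondrial mRNAs had camera adjusted p of 9.62e-06, 0.0073 and 0.036 in the other splits that keep WT libraries 1 and 2 together, against 2.27e-05 in the real one. Among the splits the call thus went with these libraries. At the preset correlation it also held without WT library 1 (camera adjusted p = 0.00374) and without WT library 2 (0.000894). An effect of losing the mitophagy receptors stays open: the targeted genes lay in opposite directions, with groups that overlapped for each.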
